A study of Mus musculus with 4 samples.

How the data were processed

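RNA sequencing was read from 4 libraries of cells sorted as mouse long-term haematopoietic stem cells (LT-HSCs), the rarest and most dormant blood-forming cells of the bone marrow. There were 2 wild-type (WT) and 2 Fam122a knockout (KO) libraries. Per the labels' protocols, each library came from sorted cells pooled from 3 animals of the C57BL/6 strain aged 8 to 12 weeks. The sort gate was lineage-negative Sca1+ Kit+ (LSK) cells without CD34 and Flk2. Libraries were made with the SMART-Seq v4 kit, which amplifies full-length cDNA from very little RNA and does not mark strand. The 2 libraries of a group came from separate pools, so gene p-values rest on the spread between libraries. That spread holds differences in library quality as well as between pools, and without WT replicate 2 it comes from the KO pair alone. The list p-values of camera at a preset correlation, described below, rest on the spread across genes.

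The deposited files hold 1 value per feature and no header. The values were taken as FPKM (fragments scaled to gene length and library size), which was inferred from the values and is not stated by the authors. Their totals were 1048000 and 1290000 in WT and 832000 and 816000 in KO, so they are not TPM. The submitters' processing notes name bcl2fastq, STAR 2.7.1a, HISAT2 2.1.0 and the genome builds GRCm38.p5 and mm10, without roles. The tool that made the values and its annotation are not given in the sources used here. Each file held 87703 features, of which 51912 were Ensembl genes and 35791 were loci with MSTRG identifiers that name no gene. The MSTRG loci held 9.14% and 53.9% of the summed FPKM in WT replicates 1 and 2, and 1.74% and 1.81% in KO replicates 1 and 2. They stayed out of the tests. Symbols were found for 51633 Ensembl genes, and 51719 were in GENCODE M21 (GRCm38), which gave the coordinates, exonic lengths and genomic spans.

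The files give no depth. In single-exon genes with 1 transcript, low values fell on steps of what 1 fragment is worth. The steps implied 4260000 and 2520000 fragments in WT replicates 1 and 2, and 6780000 and 5970000 in KO replicates 1 and 2. Between 82.7% and 89.3% of these genes lay within 0.1 of a whole number. These depths are estimates, and the limits drawn from them cover counting error only.

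Groups were compared with limma 3.58.1 (R 4.3.3), with an intensity trend, on log2(FPKM + 1), so fold changes of low genes are understated. Genes needed at least 1 FPKM in at least 2 libraries. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The test design named both a count test and this one, and the unit decided for this one. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 35 lists. The gene lists, the tests and most alternatives were fixed before the data were examined. Named genes followed a rule fixed at the same time. It took Fam122a, its relatives Fam122b and Fam122c, and Pip5k1b. As under 5 genes passed, it took the 10 genes per direction with the smallest p, a mean of at least 1 FPKM and both KO libraries on the same side of both WT libraries, leaving out predicted models and antigen receptor segments. It also took up to 4 members with the smallest p from each list discussed. The text names a part of these members, picked after their values were seen. Separately, one gene that the rule took is not reported here. Genes named outside this rule are said to be chosen after their values were seen.

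The gene test was tried on simulated data, with changed genes drawn from those with a mean log2 value above 2. Camera was run on such data too, but noise was drawn independently for each gene. That run cannot test the preset correlation, as the estimated correlation reached 0.998 in the neutrophil and granule list. With the spread of the KO pair in both groups, over 18214 genes with 50 changed at each size, changes of 1, 2, 3 and 4 on the log2 scale were recovered in 16.0%, 76.0%, 98.0% and 100% of genes. With the spread of the 4 deposited libraries, the same sizes were recovered in 0%, 0%, 2.00% and 2.00%. Alternatives covered the replicate block, the filter, the pseudocount, quantile normalization, the threshold, fry, an estimated correlation and each library left out. Alternatives on scaling, MSTRG loci, genomic span and subtraction of the WT replicate 2 profile were added after seeing the data. One subtraction was scaled to silent coding genes, under 0.5 FPKM in both KO libraries and at least 20 FPKM in WT replicate 2 (factor 0.127). It thus takes WT signal that is absent in KO as artefact, which moves genes with relatively high WT replicate 2 signal towards higher in KO. The other was scaled to MSTRG loci without use of the KO values (factor 0.138). Both set negative results to 0 and then scaled WT replicate 1 back to its former total. Genes with little WT replicate 2 signal therefore moved lower in KO, as Cd79b did after the first (log2 difference 1.33 to 1.19). Count-based alternatives were not run, since the values are not counts. Scripts used Python 3.11.15 with pandas 2.3.3.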

Results

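The series asked which genes depend on Fam122a in LT-HSCs. FAM122A is known as an inhibitor of the phosphatase PP2A. Expression was measured as FPKM in 2 WT and 2 Fam122a KO libraries, each a pool of 3 animals, at an implied depth of 2520000 to 6780000 fragments.

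The WT libraries did not resemble each other. Across 18214 genes, the log2 values of WT replicates 1 and 2 had a Pearson correlation of 0.131, against 0.967 between the KO libraries. WT replicate 1 correlated with the KO libraries at 0.834 and 0.824, and WT replicate 2 at -0.165 and -0.163. Genes are not independent replicates, so these values describe the libraries. The cytosolic ribosomal protein genes had a median of 13.02 FPKM in WT replicate 2, against 483 FPKM in WT replicate 1 and 376 and 323 FPKM in the KO libraries. Coding genes whose genomic span was over 16 times their exonic length had medians of 7.22 and 27.6 FPKM in WT and 0.92 and 1.02 FPKM in KO (3265 genes). Of 1429 olfactory and vomeronasal receptor genes, 62.8% were above 0 in each WT library, and 15.0% and 16.2% in the KO libraries. Protein-coding genes held 81.9% and 35.3% of the summed FPKM in WT, and 90.9% and 90.1% in KO. The counts of genes and lists are therefore given with and without WT replicate 2, and without it a single WT library is assumed to vary like the KO libraries.

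**Figure D1:**
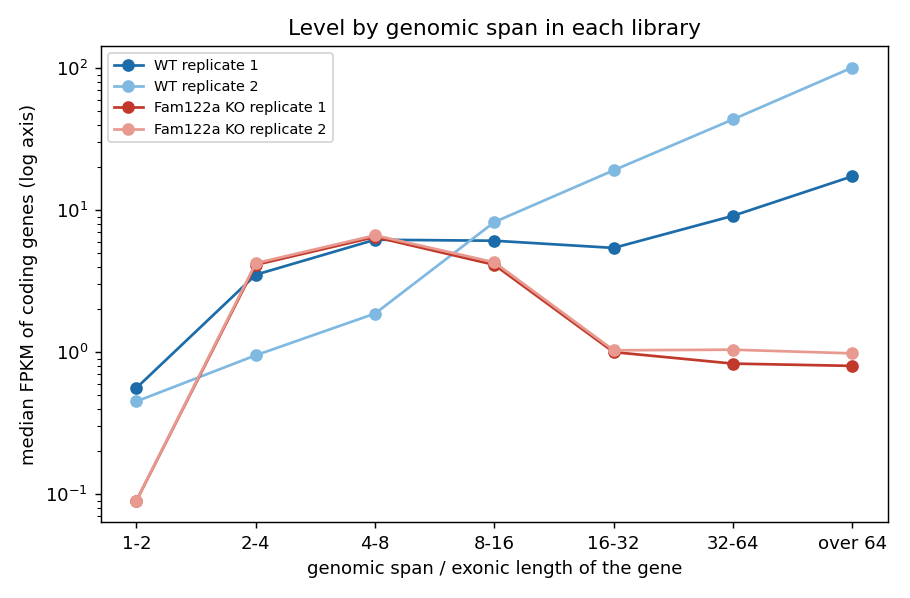
Median FPKM of coding genes (vertical, log axis) by the ratio of genomic span to exonic length (horizontal), 1 line per library. In the bin over 64 the medians were 17.3 and 101 FPKM in WT replicates 1 and 2, against 0.80 and 0.98 FPKM in the KO libraries.

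Fam122a itself was listed at 18.4 and 7.46 FPKM in the WT libraries and at 0 in both KO libraries. It is a single-exon gene of 855 bp (ENSMUSG00000074922, GRCm38 chromosome 19, 24476502 to 24477356, minus strand) inside the span of Pip5k1b. The WT values correspond to an estimated 47.3 and 12.1 fragments, and 3 fragments would have given 0.72 and 0.83 FPKM in the KO libraries. The limma test did not pass (adjusted p = 0.179). Among 62 single-exon coding genes at 5 to 40 FPKM in WT replicate 1 and above 0 in WT replicate 2, 2 were at 0 in both KO libraries, Fam122a and the vomeronasal receptor gene Vmn1r111. Without the condition on WT replicate 2, 3 of 99 were. Whether reads from the surrounding Pip5k1b span add to the WT values of Fam122a was not tested. Fam122b was at 5.63 and 0 FPKM in WT and 4.67 and 9.16 FPKM in KO. Fam122c was at 8.92 and 19.2 FPKM in WT and 0.20 and 0 FPKM in KO. The fitted log2 differences of Fam122c and Fam122a were -3.69 and -3.68, so the size of the fall alone does not single out the deleted gene. The genes are unlike, however: Fam122c has 12 exons with 995 exonic bp over chromosome X 53273424 to 53331185. It was higher in WT replicate 2 than in WT replicate 1, as were the medians of the long-span genes above, and Fam122a was not. Pip5k1b, a lipid kinase gene, was at 6.75 and 87.4 FPKM in WT and 19.0 and 21.5 FPKM in KO, so its direction depends on which WT library is used. It too is of long span, with 4035 exonic bp over 24294794 to 24555872.

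No single gene passed the test between Fam122a KO and WT. With limma, 0 of 18214 genes passed an adjusted p of 0.05, and 4070 had an unadjusted p under 0.05, of which 233 were higher and 3837 lower in KO. The smallest adjusted p was 0.179. With WT replicate 2 left out, the unadjusted balance already went the other way, with more genes higher than lower. The 10 genes with the smallest p on the higher side, none of which passed, included Mir142hg, Vpreb2, Hist1h3c, Cnn1, Spire2, Krt10, Tssk6, Cd248 and Alox15. Vpreb2, part of the surrogate light chain of B-cell precursors, was at 1.25 and 0 FPKM in WT and 47.8 and 37.9 FPKM in KO (log2 difference 4.86, SE 1.04). Alox15, a lipoxygenase gene, was at 18.7 and 1.78 FPKM in WT and 287 and 172 FPKM in KO (4.91, SE 1.3). On the lower side the 10 were Cdh13, Unc5d, Dpp6, Col24a1, Tenm4, Esrrg, Sema6d, Adcy8, Usp29 and Gli3. All 10 had genomic spans of at least 13.1 times their exonic length. Cdh13, a cadherin gene, was at 126 and 208 FPKM in WT and 0.43 and 0.18 FPKM in KO (-6.97, SE 0.94). With WT replicate 2 left out, the filter kept genes at 1 FPKM or more in both KO libraries but dropped those under 1 FPKM in both. Of these 10 lower genes, only Sema6d was then tested. The balance of counts and the list medians in that setting are shaped by this filter. They also rest on unequal FPKM totals, 1048000 in WT replicate 1 against 832000 and 816000 in KO. Scaling to equal totals was tried only with all 4 libraries, so small list medians without WT replicate 2 could change sign under it. Without WT replicate 2, 25 genes were higher and 196 lower in KO among 13848 tested. That balance turned when the WT replicate 2 profile was also subtracted from WT replicate 1, under either scaling. The subtraction itself shapes that balance, because it takes a fixed share of WT replicate 2 and lets no value fall below 0. Sema6d, high in both WT libraries, barely moved (-5.66 to -5.51). Pip5k1b, low in WT replicate 1 and high in WT replicate 2, went from 1.45 to 4.41. The turn therefore cannot tell an artefact in WT from a difference in KO. In short-span genes, those with a genomic span under 4 times their exonic length, limma passed 0 of 5727 without WT replicate 2, of which 1220 higher and 394 lower had an unadjusted p under 0.05. Without WT replicate 1, 7971 were higher and 3155 lower among 13875.

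**Figure D2:**
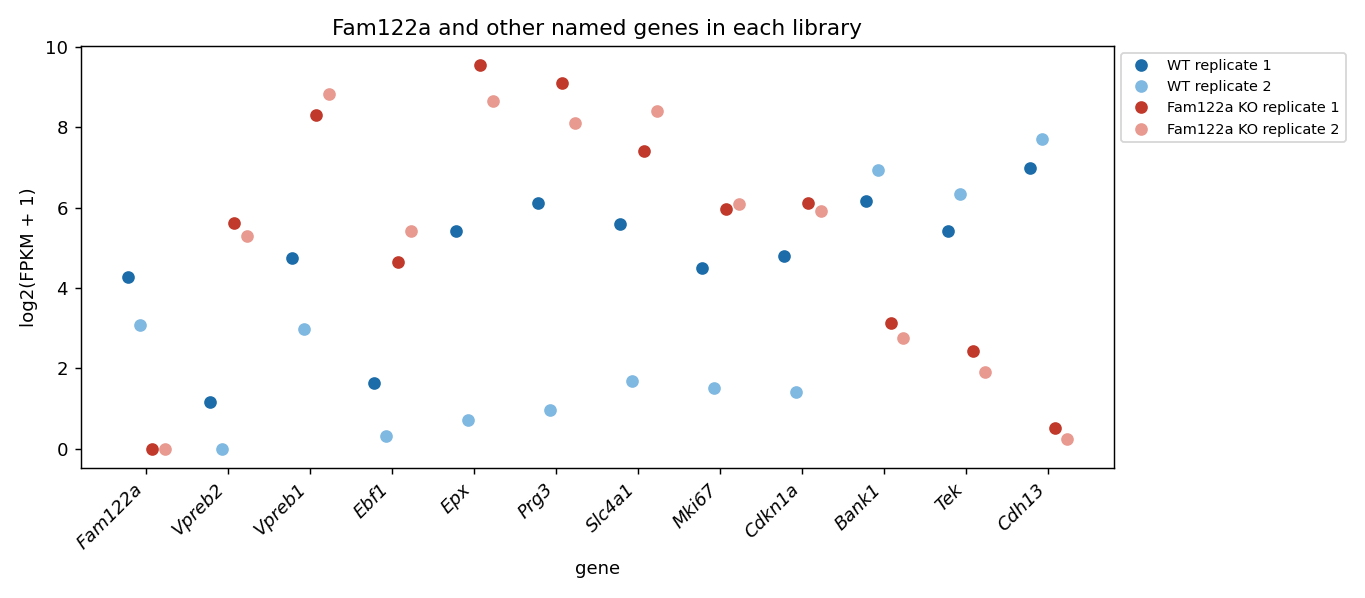
Level of Fam122a and other named genes as log2(FPKM + 1), 1 point per library. Fam122a is at 0 in both KO libraries, and Cdh13 is high in both WT libraries and near 0 in KO.

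The B cell list was higher in KO as a whole, with members on both sides. Of 22 members tested without WT replicate 2, 3 rose, 1 fell and 16 lay above 0 (median log2 difference 1.03, camera adjusted p = 0.0264, or adjusted p = 0.853 with an estimated correlation). That call did not hold when the WT replicate 2 profile was subtracted from WT replicate 1 (medians 1.11 and 1.10, adjusted p = 0.190 and 0.220) or in short-span genes without WT replicate 2 (1.16, adjusted p = 0.192). With all 4 libraries the median was 3.06 (adjusted p = 0.000323, or 0.610 with an estimated correlation), and no member passed, also adjusted over the list alone. Without WT replicate 2, Vpreb2 rose (4.28, SE 0.27) and Bank1, a B-cell signalling scaffold, fell (-3.23, SE 0.28). Bank1 was at 71.0 and 122 FPKM in WT and 7.78 and 5.73 FPKM in KO. Its value in WT replicate 2 was the highest of the 22 members. Its fall therefore cannot be told apart from the signal that sets WT replicate 2 apart. Ebf1, a transcription factor that sets B-cell fate, was at 2.1 FPKM in WT replicate 1 and 23.9 and 41.5 FPKM in KO, and did not pass. Vpreb1 and Vpreb3, chosen after their values were seen, also rose (3.81, SE 0.27, and 2.02, SE 0.18). Ms4a1, the CD20 gene of mature B cells and chosen likewise, was at 7.06 FPKM in WT replicate 1 and 2.12 and 0.89 FPKM in KO. In the list of multipotent progenitor and lymphoid priming genes, Dntt, Blnk and Rag2, which act in antigen receptor assembly and signalling, were at 14.4, 10.6 and 2.21 FPKM in WT replicate 1. In KO they were at 107 and 203, 71.1 and 138, and 12.8 and 16.2 FPKM. Ccr9, a chemokine receptor gene of the same list, was at 28.8 and 9.44 FPKM in WT and 2.19 and 3.49 FPKM in KO. None of these 4 genes passed. That list passed with all 4 libraries (median 1.36, adjusted p = 0.00154, or adjusted p = 0.610 with an estimated correlation) and not without WT replicate 2 (0.019, adjusted p = 0.982), with the filter at 5 FPKM in 2 libraries (1.85, adjusted p = 0.0505) or in short-span genes (2.75, adjusted p = 0.160).

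The dividing-cell and erythroid lists were also higher in KO. The G2, M phase and mitosis list had a median log2 difference of 2.20 with all 4 libraries and 0.65 without WT replicate 2 (camera adjusted p = 2.46e-08 and 6.6e-08), with 69 of 70 members above 0 without it. With an estimated correlation that call was lost (adjusted p = 0.610 and 0.853), and so, at the same p, were those of the S phase, erythroid, inhibitor, DNA damage, immediate early and unfolded protein lists. Mki67, a marker of cycling cells, was at 21.6 and 1.86 FPKM in WT and 61.8 and 66.6 FPKM in KO. The S phase list had medians of 2.20 and 0.41 (adjusted p = 6.29e-06 and 0.0113), and the erythroid list 3.02 and 0.96 (6.29e-06 and 5.17e-06). Slc4a1, the red-cell anion exchanger, was at 47.6 and 2.22 FPKM in WT and 168 and 340.5 FPKM in KO. The list of cell cycle inhibitors and quiescence genes was higher as well (2.27 and 0.34, adjusted p = 0.000491 and 0.0113). Its member Cdkn1a, the p21 inhibitor, was at 26.6 and 1.65 FPKM in WT and 67.9 and 59.8 FPKM in KO. DNA damage signalling and repair (0.76 and 0.40), immediate early genes (2.32 and 0.44) and the unfolded protein response (2.14 and 0.43) passed both ways too (adjusted p = 0.0114 and 0.0479, 1.09e-05 and 0.0143, and 3.9e-05 and 0.0143). After the subtraction the S phase, inhibitor, immediate early and unfolded protein calls ended (medians 0.32, 0.24, 0.33 and 0.32, adjusted p = 0.327, 0.211, 0.361 and 0.279). They also ended, as did DNA damage, in short-span genes without WT replicate 2 (adjusted p = 0.103 to 0.198). There the medians were 0.42, 0.26, 0.45 and 0.41, and 0.42 for DNA damage, over 17 to 32 members in place of 26 to 66. DNA damage did not pass with the filter at 5 FPKM in 2 libraries (median 0.76, adjusted p = 0.438) or in short-span genes (1.45, adjusted p = 0.113), and camera turned its direction without WT replicate 1 (0.99, adjusted p = 0.447). The G2, M phase and erythroid calls held in these settings. No member of these 7 lists rose past the gene test without WT replicate 2, and 1 S phase gene fell.

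The neutrophil, ribosomal protein and respiratory chain lists turned direction with the WT library used. Their medians without WT replicate 2 rest on the unequal totals given above. The neutrophil and granule list had a median of 2.94 with all 4 libraries and -0.68 without WT replicate 2 (camera adjusted p = 0.00154 and 6.11e-05), and did not pass in short-span genes with all 4 libraries (2.93, adjusted p = 0.0988). With an estimated correlation its calls were lost (adjusted p = 0.625 and 0.853), and so, at the same p, were those of the respiratory chain and ribosomal protein lists. Nuclear-encoded oxidative phosphorylation genes had medians of 2.08 and -0.34 (9.64e-06 and 2.75e-07), and cytosolic ribosomal proteins 2.07 and -0.45 (3.9e-05 and 2.65e-11). Mitochondrially encoded mRNA did not pass with all 4 libraries (0.27, adjusted p = 0.590) and was lower without WT replicate 2 (-0.79, adjusted p = 8.98e-06, or adjusted p = 0.853 with an estimated correlation). S100a8 and S100a9, neutrophil genes chosen after their values were seen, together held 12.7% of the summed FPKM in WT replicate 1, 0.02% in WT replicate 2, and 5.86% and 4.99% in KO. The 4 globin genes summed, chosen likewise, held 4.89% and 0.01% in WT replicates 1 and 2, and 7.11% and 9.62% in KO. Igkc, an immunoglobulin gene chosen likewise, was at 4768 and 1.55 FPKM in WT and 2498 and 4413 FPKM in KO. Transcripts of mature blood cells were thus abundant in WT replicate 1 and both KO libraries, so list differences cannot be assigned to stem cells alone.

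Stem cell identity genes did not pass either way (median 0.70 with all 4 libraries, camera adjusted p = 0.127, and -0.051 without WT replicate 2, adjusted p = 0.158), but did in short-span genes with all 4 libraries (2.22, adjusted p = 0.0475). Tek, a receptor kinase of stem and endothelial cells, was at 41.5 and 79.7 FPKM in WT and 4.43 and 2.74 FPKM in KO, and did not pass. PP2A subunits and regulators did not pass either way (1.43 and 0.20, adjusted p = 0.0537 and 0.321), but passed as higher without KO replicate 1 (1.15, adjusted p = 0.0416), without KO replicate 2 (1.62, adjusted p = 0.0380) and after scaling to Ensembl genes (1.40, adjusted p = 0.0467). P53 target genes passed with all 4 libraries (1.27, adjusted p = 0.00549, or adjusted p = 0.610 with an estimated correlation) and not without WT replicate 2 (0.37, adjusted p = 0.0899) or WT replicate 1 (1.98, adjusted p = 0.552), with the filter at 5 FPKM in 2 libraries (1.48, adjusted p = 0.0644) or in short-span genes (1.60, adjusted p = 0.0805). No member of these 3 lists passed, also adjusted over the list alone.

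**Figure D3:**
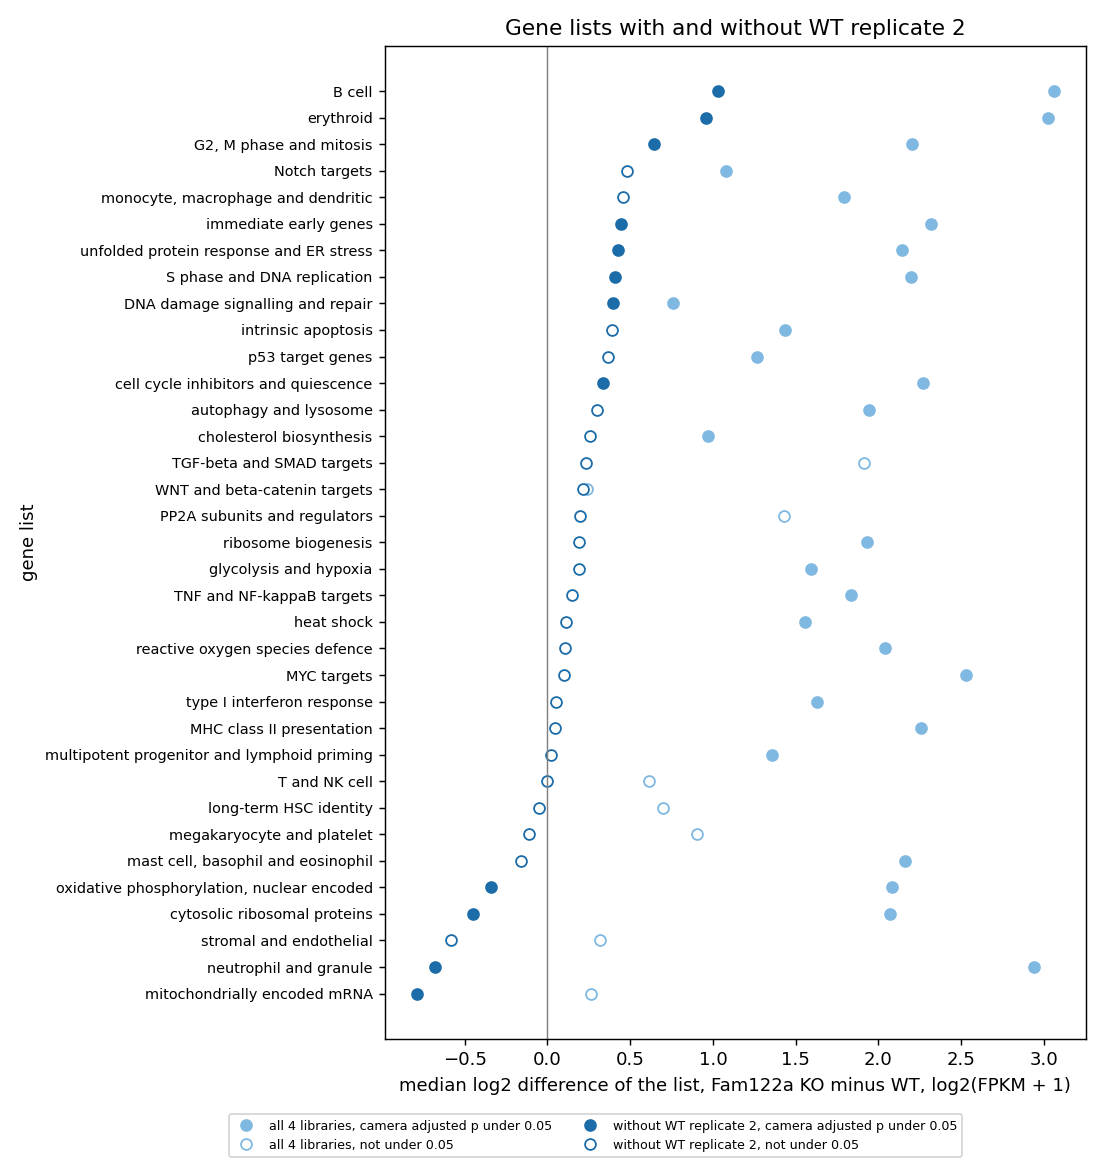
Median log2 difference, KO minus WT on the log2(FPKM + 1) scale, of each gene list with all 4 libraries and without WT replicate 2; filled points passed camera. The filled points number 27 with all 4 libraries, all above 0, and 12 without WT replicate 2, of which 4 lie below 0.

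Of the 35 lists, 27 were higher and 0 lower with all 4 libraries, and 8 were higher and 4 lower without WT replicate 2. With an estimated correlation 0 of these calls held, either with all 4 libraries or without WT replicate 2. The 8 higher lists were also higher with all 4 libraries. Besides the lymphoid priming and p53 target lists, those that passed with all 4 libraries and not without WT replicate 2 had medians, without it, of 0.46 (monocyte, macrophage and dendritic), 0.05 (MHC class II presentation), -0.16 (mast cell, basophil and eosinophil), 0.39 (intrinsic apoptosis), 0.05 (type I interferon response) and 0.15 (TNF and NF-kappaB targets). The others were 0.11 for heat shock, 0.11 for reactive oxygen species defence, 0.19 for glycolysis and hypoxia, 0.19 for ribosome biogenesis, 0.10 for MYC targets, 0.48 for Notch targets, 0.26 for cholesterol biosynthesis and 0.30 for autophagy and lysosome. Of these, Notch targets did not pass with any 1 library left out (adjusted p = 0.0996 to 0.733), and mast cell, intrinsic apoptosis and heat shock did not pass without WT replicate 1 (0.319, 0.0548 and 0.0613). Megakaryocyte and platelet (-0.11), T and NK cell (-0.01), stromal and endothelial (-0.58), WNT and beta-catenin target (0.22) and TGF-beta and SMAD target (0.23) lists passed neither way. Without KO replicate 2, however, the megakaryocyte (1.28, adjusted p = 0.0127) and TGF-beta (1.91, adjusted p = 0.0380) lists passed as higher. The TGF-beta list also did in short-span genes (2.17, adjusted p = 0.0394), and the WNT list passed as lower without WT replicate 1 (-0.67, adjusted p = 0.0454). Without WT replicate 2, camera gave the lymphoid priming and interferon lists the lower and the mast cell, basophil and eosinophil list the higher direction, against the sign of their medians. Znrf3, a WNT pathway inhibitor, was the only member of any list to pass adjusted over the list alone with all 4 libraries, at 172 and 125 FPKM in WT and 3.94 and 1.94 FPKM in KO. Over all genes it did not pass (limma adjusted p = 0.179). High in both WT libraries and low in KO, it resembled Cdh13 and the other long-span genes on the lower side. Whether its fall shares their source was not tested.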

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

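Of the tests below, those on the correlation with precursor RNA and on subtraction for the G2 and M phase list were set before their result was seen, and the others after it.

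Signal appeared at unannotated loci that the comparisons do not use. Of the MSTRG loci, 2 were at 5 FPKM or more in both KO libraries and at 0 in both WT libraries, and 787 showed the opposite.

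WT replicate 2 stood apart from the other 3 libraries. An intact RNA library that was shallow or of another tissue is argued against by its ribosomal protein median of 13.02 FPKM. Genomic DNA in the library remains a candidate source: across coding genes its FPKM followed genomic span over exonic length (Spearman rho 0.428). Unspliced precursor RNA met its own test too, with a rho of 0.329 against the KO mean among long-span genes, so it stays open there. For WT replicate 1 that rho was 0.76. Precursor RNA also covers the genomic span, so these 2 tests do not separate it from genomic DNA. Precursor RNA is argued against for the olfactory and vomeronasal receptor genes, whose mean was 3.52 FPKM against 0.78 FPKM in WT replicate 1 and at most 0.20 FPKM in KO, although the share of them above 0 was 62.8% in each WT library and does not separate the pair.

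The B cell list was higher in KO than in WT replicate 1, and DNA-like signal in that library cannot be told apart as a partial cause, because the call ended when the WT replicate 2 profile was subtracted (adjusted p = 0.0264 before, 0.190 and 0.220 after). Its median went from 1.03 to 1.11 (quartiles -0.23 and 2.35, then -0.37 and 2.21) and its mean from 1.08 to 1.04 (SE over members 0.41 both times), while the mean of all genes tested, against which camera sets a list, went from -0.011 to 0.20. B-lineage cells carried over in the sorted KO pools may contribute, but the share of members higher by over 1 on the log2 scale was 50% of 22, between the bounds set, although the LSK gate should remove such cells. That share was computed over 3 gene sets: 87.0% of 23 B-cell precursor and eosinophil genes picked after their values were seen, then 45.2% of 42 members of the B cell and the mast cell, basophil and eosinophil lists, then the B cell list, of which the first is circular and the second would have argued against carried-over cells. Chance differences between pools and an effect of Fam122a cannot be told apart with 1 usable WT library, as the KO libraries differed by 35.9% of the difference between KO and WT replicate 1.

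The G2 and M phase genes were higher in KO than in WT replicate 1. DNA-like signal in WT replicate 1 cannot be told apart as a partial cause: subtraction took the list's median, less that of all genes, from 0.53 to 0.33. Dividing erythroid or B-cell precursors carried over may also contribute, although the lineage-negative LSK gate should remove both. The list met the test set for this, being higher in KO replicate 2 than in KO replicate 1 (median log2 ratio 0.30, 69 of 70 members). The erythroid list was too (0.61, 36 of 38), against 7308 of 13848 among all genes tested. That test cannot single out such cells, because members of a list are not independent replicates and other lists also passed it. S phase was higher (52 of 59, exact sign test p = 1.36e-09), and ribosomal proteins were lower, with 7 of 78 higher (p = 1.93e-14). The B cell list did not pass that exact sign test (0.39, 16 of 22, p = 0.0525). An effect of Fam122a on division stays open and was not tested apart from these.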

How the results depend on the processing

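The scaling, MSTRG, short-span and subtraction alternatives were chosen after seeing the data, and the count-based ones planned for each result were not run. The count of genes stayed at 0 with the replicate block, the other filters, pseudocount, quantile normalization, scaling, threshold and fold, and became 710 (10 higher) with MSTRG loci included, 285 (152 higher) and 416 (261 higher) after the WT replicate 2 profile was subtracted (scaled to silent genes and to MSTRG loci, WT replicate 2 left out), and 0 to 11126 with 1 library left out. The count of lists, 27, was 28 with the replicate block, which added PP2A (adjusted p = 0.0287) and TGF-beta (0.0367) and lost Notch (0.0502), although the libraries share only a number (their deviations correlated at 0.055), 0 with an estimated correlation, 0 with fry, 19 with the strict filter, 20 with short-span genes, 6 with short-span genes and WT replicate 2 left out, 7 and 7 after the subtractions, and 12 to 29 with 1 library left out. Calls ended with the strict filter for lymphoid priming, p53, DNA damage, monocyte (adjusted p = 0.0871), MHC class II (0.0644), heat shock (0.0767) and cholesterol (0.0767), and with short-span genes for lymphoid priming, neutrophil, p53, DNA damage, mast cell (0.277), heat shock (0.180), oxygen species (0.0811) and cholesterol (0.141). Too few Notch targets were left to test with the strict filter, and too few MHC class II and stromal genes with short-span genes. Fam122a had a fitted difference of -3.68, and no value with either WT library left out, as it then failed the filter. The short-span filter alone turned no list. Directions turned, with medians for short-span genes with WT replicate 2 left out, both subtractions and the range over left-out libraries in that order, for long-term HSC identity (0.046, 0.088, 0.091, -0.051 to 1.19), lymphoid priming (0.069, -0.097, -0.10, 0.019 to 2.97), megakaryocyte (-0.089, -0.020, -0.017, -0.11 to 2.01), neutrophil (-0.72, -0.82, -0.82, -0.68 to 6.63), T and NK cell (0.034, 0.066, 0.059, -0.005 to 1.24), interferon (0.17, 0.024, 0.020, 0.049 to 3.09), oxidative phosphorylation (-0.29, -0.47, -0.47, -0.34 to 4.33), mitochondrial mRNA (-0.79, -0.91, -0.91, -0.79 to 1.33) and ribosomal proteins (-0.44, -0.59, -0.60, -0.45 to 4.70). They turned without the range for mast cell (-0.28, 0.32, 0.43), TNF (0.13, 0.075, 0.076), heat shock (0.041, 0.017, 0.026), oxygen species (-0.20, 0.11, 0.12) and cholesterol (0.16, 0.15, 0.14). After the subtractions alone they turned for MHC class II (-0.094, -0.10), ribosome biogenesis (0.11, 0.12) and MYC targets (-0.033, -0.038), and only with short-span genes and WT replicate 2 left out for monocyte (0.23). The WNT list turned with short-span genes and WT replicate 2 left out (0.21), fry (0.24), the strict filter (0.29) and left-out libraries (-0.67 to 0.22), and mitochondrial mRNA with the strict filter (0.27). Stromal (-0.58 to 0.69) and DNA damage (0.40 to 0.99) lists turned with a library left out. Directions are those of camera, which can differ from the median's sign. Among named genes, Pip5k1b turned after subtraction (4.41, left-out range -2.06 to 1.45), as did Mcpt8 (-0.49, -0.34 to 5.11) and Prss34 (-0.38, -0.24 to 4.77). The cause was not tested beyond the tests on WT replicate 2. The all-gene median log2 difference was 0.22, and -0.34 with no filter, 1.05 with the strict filter, 0.95 in short-span genes, -2.15 with MSTRG loci, 0.10 after scaling, 1.61 without WT replicate 1 and 0.12 without WT replicate 2. It lay from 0.20 to 0.30 in the other settings. The implied depth, lowest in WT replicate 2 at 2520000 fragments, limits low genes.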

Other observations

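The mast cell, basophil and eosinophil list did not pass without WT replicate 2 (median -0.16, camera adjusted p = 0.982), and its members lay on both sides. Its 4 members with the smallest p were Epx, Prg3 and Ear6, which encode eosinophil granule proteins, and Siglecf, an eosinophil surface receptor. They were at 41.8, 67.7, 172 and 4.11 FPKM in WT replicate 1. In the KO libraries Epx was at 748 and 403 FPKM, Prg3 at 550.1 and 277 FPKM, Ear6 at 1118 and 495 FPKM, and Siglecf at 21.7 and 9.34 FPKM. The basophil protease genes Mcpt8 and Prss34, chosen after their values were seen, were at 97.3 and 236 FPKM in WT replicate 1. In KO they were at 81.1 and 72.2 FPKM and at 205 and 194 FPKM. None of these 6 genes passed the limma test with all 4 libraries or without WT replicate 2, and no difference between eosinophil and basophil genes was tested.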
